A study of Mus musculus with 54 samples.

How the data were processed

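RNA was measured in 54 mouse libraries from defined stages of lung cancer in a genetically engineered model. Per the labels, tumours were started by lentiviral Cre in mice of the strain 129S1/SvImJ that carry an inducible oncogenic Kras allele, a floxed p53 gene and a tdTomato reporter (KPT), and Tomato-positive cancer cells were purified before RNA extraction. The 3 KT hyperplasia libraries come, per the labels, from mice without the floxed p53 allele. The normal lung libraries carry the KPT genotype in the labels, and whether those cells were sorted is not given in the sources used here. Per the labels, RNA was extracted with the Qiagen AllPrep kit and libraries were made with the Ovation RNA-Seq system and the TruSeq DNA kit. Reads were 100 bp paired-end and were aligned to mm10, per the series description and the submitters' processing notes. That description counts fewer samples and names a late KP group where the labels have KT hyperplasia, and the labels were followed.

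The deposited table holds 27782 genes in 54 libraries as TPM, a share of all transcripts scaled to 1000000, summarised per gene by the authors with Sailfish, per the file headers. The version is not given in the sources used here. A first line of the same table calls the values FPKM, but each library sums to between 999999.5 and 1000000.2, so the deposited values were read as TPM. TPM keep no depth, so the number of reads behind each value is unknown, and no counting interval can be given. TPM are shares of a fixed total, so genes that take a large part of a library lower all others. The most abundant were Gm42418, an rRNA-like gene model with a mean of 56013 TPM, and Sftpc, which reached 211439 TPM in 1 library. Between 12724 and 16747 genes per library were at 1 TPM or more, and 1319 genes were at 0 in every library. How reads shared between gene copies were divided is known only as far as the Sailfish name tells, so values of close paralogs and immunoglobulin genes are uncertain. Gene symbols were matched by Ensembl identifier for 27301 genes (98.3%), and coordinates come from the GENCODE annotation of GRCm38, the assembly also called mm10.

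Groups were taken from the stage given in the labels, and the animal from the code that opens the sample titles. The labels do not say outright that this code is the mouse. It was read so, which gave 18 mice, and normal lung has no code. In the stage comparisons tumour cells from the pleural cavity were counted among the metastases. Metastases of 1 mouse were averaged on the log2 scale before these comparisons, and soft tissue metastases of 1 mouse before the site comparisons. By the codes, each primary tumour group holds 1 library per mouse. The values labelled non-metastatic primary tumour 1 do not belong to the mouse of their code, CC0299, and if they are of CC0302 that group holds 2 tumours of CC0302 and none of CC0299. Within a group the spread is therefore that between mice if the codes are mice, and for normal lung only that between its libraries. Each fit pooled this spread over all its groups, because several hold only 2 or 3 samples. The p-values thus do not rest on the spread of the compared groups alone, and those for normal lung rest mostly on the spread of other groups. Samples of 1 mouse in different groups were taken as unrelated in the main fits, so these p-values ignore the pairing. With the mouse as a random effect the correlation within mice was 0.36 in stages and 0.7 in sites. Deviations of samples with the same code from their group means were correlated across genes as a check of reading the codes as mice. For metastatic primary tumours and metastases, r lay between 0.17 and 0.62 and above 0.1 in 9 of 9 mice. Between the kinds of primary tumour r was above 0.1 in 4 of 8 mice, and between non-metastatic primary tumours and metastases in 5 of 10. The lowest r was 0.56 for pleural and lymph node metastases (4 mice), 0.71 for pleural-cavity cells and lymph node metastases (3 mice) and 0.31 for soft tissue and lymph node metastases (4 mice).

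All tests were two-sided and used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(TPM + 1), with Benjamini-Hochberg adjustment over the 18342 genes with at least 1 TPM in at least 3 libraries and a threshold of 0.05. Fold changes are on this log2(TPM + 1) scale, which understates changes of low genes. One fit held the stages, with metastases of 12 mice, and another the sites of metastasis, in both cases without the mouse as a block. The 33 gene lists, with 517 of 522 members in the table, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Members were counted with the adjustment over all genes and with the adjustment over the list alone. Groups, gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. Under that rule, the genes named are the 8 largest changes each way in the 3 comparisons around primary tumours and the 5 largest in the others, among genes past the threshold at 5 TPM or more in the higher group that kept their sign with any sample left out. Up to 4 members of a list with the smallest p and 20 focal genes were added. Aspn and Nkx2-1 levels of single libraries were singled out after the values were seen.

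Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The fits were tested on simulated data with 200 of 18342 genes changed. Of 4-fold changes, 83% were recovered for p53-deficient against KT hyperplasia, 80% for p53-deficient hyperplasia against normal lung and 91% for non-metastatic primary tumours against p53-deficient hyperplasia. The share was 95% between the kinds of primary tumour, 97% for metastases against non-metastatic and 95% against metastatic primary tumours. Among sites it was 84% for pleural, 75% for pleural-cavity and 94% for soft tissue samples against lymph node metastases, and 72% for liver against soft tissue metastases. Of 2-fold changes far fewer were recovered among sites, 30%, 27%, 47% and 25% in the same order. For the stage comparisons, in the order above, the shares were 35%, 41%, 58%, 78%, 78% and 86%. Only genes with an average level of about 5 TPM or more were changed in the simulations. Alternatives were another pseudocount, other filters on low values, median-of-ratios and quantile scaling, fits of only the groups compared, array weights, covariates for leukocyte genes and for genes detected, the mouse as a block or random effect, every library as its own sample, and each sample left out in turn. After the data had been seen, fits without a pair of nearly identical libraries, without leukocyte-rich libraries and without the metastases of 1 mouse were added, as were exact sign flips of tumour positions within mice. The labels give no batch or date, so none could be tested.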

Results

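The 54 libraries comprised 2 of normal lung, 3 of KT hyperplasia, 3 of p53-deficient hyperplasia, 10 of non-metastatic and 9 of metastatic primary lung tumours, 9 of lymph node, 4 of pleural, 3 of liver and 8 of soft tissue metastases, and 3 of tumour cells from the pleural cavity, which count as metastases in the comparisons with primary tumours. KT hyperplasia is the early lesion made by oncogenic Kras with p53 intact, and p53-deficient hyperplasia the same stage with p53 deleted. Each value is the TPM of a gene, with unknown depth. A number given alone after a gene is its log2 fold change. Genes at 1 TPM or more numbered 16426 to 16747 in normal lung and 12724 to 15307 in all other libraries. The libraries labelled non-metastatic primary tumour 1 and metastatic primary tumour 2, which carry the codes of different mice, held nearly the same values, and n counts them by code. The SD of their log2 ratio was 0.0145 over 15107 genes, against 0.301 for the next closest of the 1431 pairs. Both were kept in the fits, and counts without both are given where they differ by more than 1.5 times.

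The targeted gene was examined first. Trp53, which encodes the tumour suppressor p53 (ENSMUSG00000059552, mm10 chromosome 11, 69580359 to 69591873), was at 6.40, 9.13 and 6.77 TPM in p53-deficient hyperplasia 1, 2 and 3 and at 15.8, 22.6 and 28.4 TPM in KT hyperplasia 1, 2 and 3. Normal lung 1 and 2 held 74.3 and 55.4 TPM. Trp53 was at 6.14 to 12.1 TPM in non-metastatic primary tumours, 5.63 to 12.3 TPM in metastatic primary tumours and 4.24 to 18.7 TPM in metastases. Lymph node metastasis 6 and pleural metastases 3 and 4, at 17.9, 18.7 and 17.3 TPM, exceeded KT hyperplasia 1. The table gives 1 value per gene, so reads from exons outside the deletion are included.

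The comparison of p53-deficient with KT hyperplasia asks what differs between the genotypes at the earliest stage. All KT codes open with DC and all p53-deficient hyperplasia codes with CC. The p53 genotype therefore cannot be told apart from other differences between these series of mice. Airway genes were far lower in p53-deficient hyperplasia. Scgb1a1, the secretoglobin of club cells (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), was at 901 ± 623 TPM in p53-deficient and 30450 ± 7340 TPM in KT hyperplasia (SD, n = 3 each), a log2 fold change of -5.32 (SE 1.17, adjusted p = 0.00543). Of 15 club and ciliated airway genes 4 fell and 0 rose, and 10 fell adjusted over the list alone, with a list median of -2.35 (camera adjusted p = 2.21e-26, and adjusted p = 5.26e-05 with an estimated correlation). Foxj1, the regulator of motile cilia, fell by 3.44 (SE 0.34), from 27.8 ± 12.7 to 1.79 ± 1.80 TPM, and Scgb3a1 and Ccdc153 had log2 fold changes of -4.90 and -2.40. Scgb1a1, Scgb3a1 and Ccdc153 did not pass among genes with a mean of 5 TPM or more (adjusted p = 0.054, 0.154 and 0.0559), in a fit of only these groups (adjusted p = 0.0998, 0.215 and 0.378) or without p53-deficient hyperplasia 1 and KT hyperplasia 3, which were rich in leukocyte RNA (adjusted p = 0.0981, 0.452 and 0.291). Foxj1 did not pass in a fit of only these groups (adjusted p = 0.174). Ltf, which encodes the secreted iron-binding protein lactoferrin, and Cckar, a cholecystokinin receptor, had log2 fold changes of -5.71 and -3.30. Ltf, like Scgb1a1, did not pass among genes with a mean of 5 TPM or more, in a fit of only these groups or without the leukocyte-rich libraries (adjusted p = 0.0538, 0.0641 and 0.119).

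Immediate early and heat shock genes, which respond within minutes to growth signals and to tissue handling, were also lower in p53-deficient hyperplasia. Of 16 members of that list 3 fell and 0 rose, and 14 fell adjusted over the list alone (median -1.92, camera adjusted p = 2.21e-26, and adjusted p = 0.00528 with an estimated correlation). The log2 fold changes of Fos, Jun and Egr1 were -2.53, -2.04 and -2.23. Each of these lost its call in 4 of 6 fits with 1 library left out, and without the leukocyte-rich libraries they were at -1.85, -1.46 and -1.44 (adjusted p = 1 for each). Of 22 p53 target genes 1 fell, the cyclin gene Ccng1 (-0.91, SE 0.22, adjusted p = 0.0146, but 0.109 among genes with a mean of 5 TPM or more, 0.138 in a fit of only these groups and 0.12 without the leukocyte-rich libraries), and 3 fell adjusted over the list alone (median -0.278, camera adjusted p = 3.74e-05, and adjusted p = 0.0193 with an estimated correlation). Ccng1 also lost its call in 4 of 6 fits with 1 library left out. Cdkn1a, the p53-induced inhibitor of the cell cycle, was at 106 ± 23.3 against 382 ± 97.6 TPM, without overlap between the groups. With the spread pooled over all stages it did not pass (-1.83, adjusted p = 0.524). Neither did Phlda3 (-2.21, adjusted p = 0.204) or the death effector Bax (-0.88, adjusted p = 0.0678), which passed under both other scalings. Trp53 itself fell by 1.44 (SE 0.31, adjusted p = 0.00376). The alveolar regulator Nkx2-1 and the surfactant gene Sftpc differed by 0.15 and 0.24 and did not pass (adjusted p = 1 for both).

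In all, 249 genes passed the threshold, 5 higher and 244 lower in p53-deficient hyperplasia. The 5 higher were Ddx47, an RNA helicase (1.13), the histone deacetylase Hdac1 (1.12), the tubulin ligase family gene Ttll12 (0.86), and the immunoglobulin genes Ighv2-2 (2.45) and Igkv4-59, which was listed at 0 in KT hyperplasia. Values of immunoglobulin genes are uncertain, since reads may be split between copies, and the leukocyte gene Ptprc was at 11.1 TPM in p53-deficient hyperplasia 1 and 13.1 TPM in KT hyperplasia 3. The count was 160 with a pseudocount of 0.1, 9 among genes with a mean of 5 TPM or more, 3 in a fit of only these groups, 548 with array weights, 148 without those leukocyte-rich libraries and 156 without KT hyperplasia 1. Of the 16 named genes past the threshold 5 stayed past it with any 1 library left out. Without p53-deficient hyperplasia 1, 2 and 3 the calls lost were 6, 2 and 9, and without KT hyperplasia 1, 2 and 3 they were 9, 3 and 9. In a fit of only these groups 15 of the 16 were lost, all but Cckar, and without the leukocyte-rich libraries 12. Trp53 lost its call without KT hyperplasia 3 (-1.25, adjusted p = 0.0704), without the leukocyte-rich libraries (-1.16, adjusted p = 0.314) and in a fit of only these groups (adjusted p = 0.174).

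**Figure D1:**
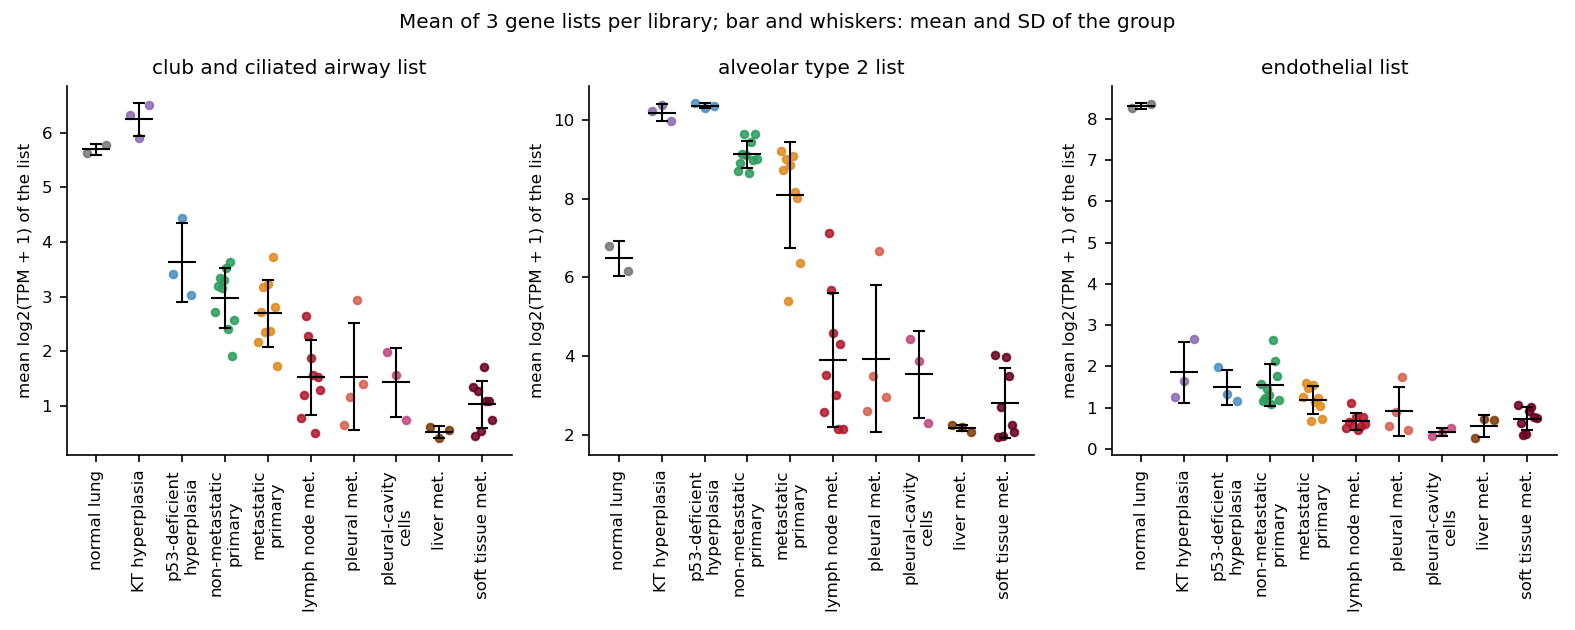
Mean log2(TPM + 1) of the airway, alveolar type 2 and endothelial gene lists in each library (points), with the mean and SD of each group (bar and whiskers). Of list members at 5 TPM or more in normal lung, airway genes in KT hyperplasia lay a median of 0.4 below normal lung on the log2 scale and endothelial genes 6.34 below.

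Set against normal lung, p53-deficient hyperplasia was rich in transcripts of alveolar type 2 cells, the surfactant-making cells of the alveolus, and poor in those of vessels and stroma. The endothelial list mean was 8.25 and 8.36 in normal lung 1 and 2 and 1.98, 1.34 and 1.16 in p53-deficient hyperplasia 1, 2 and 3 (log2). Normal lung thus held much RNA of other cell types, while the hyperplasia cells were purified per the labels. Differences in cell make-up and changes within lesion cells cannot be told apart for any gene of this comparison. Of 20 alveolar type 2 genes 18 rose and 0 fell, and 19 rose adjusted over the list alone (median 4.03, camera adjusted p = 1.37e-12, but adjusted p = 0.177 with an estimated correlation). Sftpc, which encodes surfactant protein C (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081), was at 204400 ± 6577 TPM against 5984 ± 2331 TPM (SD, n = 3 and 2; log2 fold change 5.15, SE 1.62, adjusted p = 0.00921). The protease gene Napsa rose by 4.69, the surfactant lipid transporter gene Abca3 by 3.12 and the transcription factor gene Etv5 by 2.73. Genes of fatty acid and surfactant lipid synthesis rose with them, 10 of 18 higher and 1 lower, and 10 and 2 adjusted over the list alone (median 1.35, camera adjusted p = 1.2e-08, and adjusted p = 0.0351 with an estimated correlation). Among them were the desaturase Scd1 (5.36), fatty acid synthase Fasn (4.24) and malic enzyme Me1 (3.16).

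All 13 endothelial genes fell, also adjusted over the list alone (median -6.8, camera adjusted p = 4.85e-18, and adjusted p = 0.0351 with an estimated correlation). Ramp2 had a log2 fold change of -9.18, the endothelial cadherin gene Cdh5 of -8.72, the receptor genes Kdr and Tek of -5.62 and -7.15, and Calcrl, Thbd and Gpihbp1, further genes of vessel lining, of -8.71, -8.69 and -8.50. Of 14 fibroblast and vessel muscle genes 11 fell by both adjustments (median -3.88, camera adjusted p = 0.0047, but adjusted p = 0.604 with an estimated correlation). Dcn was at -5.23 and Tagln at -4.26. All 16 immediate early genes fell by both adjustments (median -4.25, camera adjusted p = 9.26e-07, but adjusted p = 0.29 with an estimated correlation). Egr1, Zfp36 and Ier3 were at -5.16, -5.08 and -4.99. Of 20 interferon response genes 18 fell, and 19 adjusted over the list alone (median -2.47, camera adjusted p = 1.09e-06, but adjusted p = 0.227 with an estimated correlation). Ifit1 was at -4.35 and Irf9 at -3.19. Of the 22 p53 targets 1 rose and 10 fell, and 3 rose and 10 fell adjusted over the list alone. The list did not stand apart from other genes (median -0.917, camera adjusted p = 0.587). Mdm2 and Cdkn1a had log2 fold changes of -2.05 and -4.58. Trp53 fell by 2.96.

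In all, 8370 genes passed, 1235 higher and 7135 lower. The other genes named by size were Gkn2, a gastrokine at 215 ± 147 TPM that was listed at 0 in both normal lung libraries, Tmem213 (6.79), the kininogen gene Kng2 (5.41) and Fbp2, of gluconeogenesis (5.24). The median of all genes was -0.548 on the deposited scale, -0.0288 after median-of-ratios scaling, which called 3176 higher and 3691 lower, and 0.11 after quantile normalization, which called 3842 higher and 3151 lower. With genes detected as a covariate 3742 genes passed, and among genes with a mean of 5 TPM or more 4662. Of the 28 named genes past the threshold 2 lost it without normal lung 2, Fbp2 and Sftpc, the latter also after quantile normalization. With genes detected as a covariate 2 others were lost, Etv5 and Dcn.

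The step from p53-deficient hyperplasia to non-metastatic primary tumours brought up some genes of the gut, liver and embryo and brought down some of antigen display and of alveolar type 2 cells. Of these lists that of antigen display alone passed with an estimated correlation. Hmga2, an oncofetal chromatin gene (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), was at 18.2 ± 14 TPM in the tumours and 1.5 ± 0.369 TPM in hyperplasia (SD, n = 10 and 3; log2 fold change 2.54, SE 0.74, adjusted p = 0.026, but 0.0653 with leukocyte genes as a covariate and 0.128 without the leukocyte-rich hyperplasia libraries). Of 12 oncofetal genes 4 rose and 0 fell, and 5 rose adjusted over the list alone, including the mRNA-binding protein gene Igf2bp2 (2.43), alpha-fetoprotein Afp (2.32) and Sox9 (1.62; list median 1.39, camera adjusted p = 0.0336, but adjusted p = 0.368 with an estimated correlation). Of 20 gastric and gut genes 5 rose and 0 fell by both adjustments, among them the transcription factor genes Hnf4a (2.08) and Hnf1a (1.96), cathepsin E Ctse (2.63) and the mucin gene Muc5ac (2.07; list median 2.02, camera adjusted p = 0.0339, but adjusted p = 0.571 with an estimated correlation). Of 14 hepatocyte genes 3 rose, and 5 adjusted over the list alone, the 3 being Apob (3.26), Hpx (1.55) and Ahsg (1.14), the last 2 at under 5 TPM (list median 1.18, camera adjusted p = 0.035, but adjusted p = 0.43 with an estimated correlation). Without the leukocyte-rich hyperplasia libraries Hnf4a, Hnf1a, Ctse and Muc5ac did not pass (adjusted p = 0.191, 0.14, 0.153 and 0.166), and neither did Sox9, Apob, Hpx and Ahsg (adjusted p = 0.199, 0.185, 0.0662 and 0.183). With leukocyte genes as a covariate Hnf4a, Ctse, Muc5ac, Sox9, Apob and Ahsg did not pass (adjusted p = 0.0937, 0.0558, 0.0667, 0.0814, 0.0786 and 0.0851). Muc5ac and Apob each lost the call in 10 of 13 fits with 1 library left out, and Muc5b, named below, in 11.

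Antigen display genes of MHC class I were lower in the tumours. Of 12 members 4 fell and 0 rose, and 8 fell adjusted over the list alone (median -1.30, camera adjusted p = 3.47e-15, and adjusted p = 0.0314 with an estimated correlation). B2m, the shared light chain, fell from 1425 ± 269 to 361 ± 123 TPM (-2.02), and the log2 fold changes of the regulator Nlrc5, the peptide transporter gene Tap2 and H2-D1 were -1.36, -0.82 and -1.46. Tap2 and H2-D1 did not pass without the leukocyte-rich libraries (adjusted p = 0.113 and 0.14). Macrophage genes moved the same way, with 5 of 16 lower and 7 adjusted over the list alone (median -0.896, camera adjusted p = 5.07e-12, but adjusted p = 0.121 with an estimated correlation), among them Fcer1g (-2.85), Tyrobp (-3.28) and Ear2 (-3.25). With leukocyte genes as a covariate these were at -1.41, -1.51 and -1.57, and without the leukocyte-rich hyperplasia libraries at -1.92, -2.27 and -2.10, and did not pass in either case. The macrophage list median was then -0.0519 and -0.122. Of 20 alveolar type 2 genes 3 fell by both adjustments, Etv5 (-1.84), Lamp3 (-2.73) and the complement gene Hc (-3.65; list median -1.35, camera adjusted p = 1.63e-10, but adjusted p = 0.136 with an estimated correlation). Of 15 airway genes 3 fell, and 4 adjusted over the list alone (median -0.757, camera adjusted p = 1.04e-07, but adjusted p = 0.0572 with an estimated correlation). Cyp2f2 was at -2.20 and Dynlrb2 at -1.89. Of 18 lipid synthesis genes 4 fell and 1 rose, and 5 and 1 adjusted over the list alone (median -0.42, camera adjusted p = 4.52e-09, and adjusted p = 0.0314 with an estimated correlation). Scd1 was at -2.93, Fasn at -1.28 and Elovl1 at -2.28, and Elovl6 higher by 1.55.

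Of single genes, Kras rose from 81.1 ± 12.4 to 184 ± 34 TPM (1.16, SE 0.19, adjusted p = 0.000232) and the tumour suppressor gene Cdkn2a rose by 2.51. Myc was higher by 1.43 (adjusted p = 0.0166), but did not pass with leukocyte genes as a covariate (adjusted p = 0.0514), without the leukocyte-rich libraries (adjusted p = 0.0966) and in 2 of 13 fits with 1 library left out. The largest rises beside those named were in the growth factor binding gene Igfbp3 (3.10), the mucin gene Muc5b (3.06), the glutathione transferase gene Gstm5 (2.85), the transcription factor gene Myrf (2.77), the zinc finger gene Zfp239 (2.71), and Akr1c12 and Akr1c13 (3.24 and 2.83), neighbouring aldo-keto reductase copies whose values are uncertain. The largest falls were in the resistin-like gene Retnla (-4.64), the chitinase gene Chia1 (-4.24), the carbonyl reductase gene Cbr2 (-4.17), the homeobox gene Irx2 (-4.01) and the peptidase gene Mme (-3.74), with H2-Q7 (-4.66) and Lyz1 (-4.52) uncertain as genes with close copies. Igkc (-5.30), uncertain as an immunoglobulin gene, lost its call without the leukocyte-rich libraries and with leukocyte genes as a covariate. Trp53 (0.13), Nkx2-1 (0.17) and Sftpc (-1.68, adjusted p = 0.332, and 0.0283 in a fit of only these groups) did not pass.

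In all, 2070 genes passed, 1750 higher and 320 lower. The direction of that total depended on scale. The median of all genes moved from 0.277 to -0.00855 after median-of-ratios scaling, which called 196 higher and 660 lower, and to 0.028 after quantile normalization, which called 273 higher and 549 lower. The count was 1378 among genes with a mean of 5 TPM or more, 7917 with array weights, 1145 with leukocyte genes as a covariate, 295 with genes detected as a covariate (107 higher, 188 lower) and 1324 without both nearly identical libraries. It was 288 without the leukocyte-rich hyperplasia libraries (184 higher, 104 lower), 316 without p53-deficient hyperplasia 1, 308 without p53-deficient hyperplasia 3 (99 higher, 209 lower) and 3200 without non-metastatic primary tumour 9. Without the leukocyte-rich libraries the gastric, oncofetal and hepatocyte lists did not pass (camera adjusted p = 0.0959, 0.0668 and 0.0949). Neither did the oncofetal and hepatocyte lists with leukocyte genes as a covariate (camera adjusted p = 0.0784 and 0.149), the gastric and hepatocyte lists among genes with a mean of 5 TPM or more (camera adjusted p = 0.0673 and 0.102) or the hepatocyte list in a fit of only these groups (camera adjusted p = 0.142). Of the 45 named genes past the threshold 19 stayed past it with any 1 library left out. Calls lost were 24, 7 and 23 without p53-deficient hyperplasia 1, 2 and 3, 24 without the leukocyte-rich libraries, 21 with genes detected and 18 with leukocyte genes as a covariate, and 11 under each other scaling. Beside those given above, the calls lost without the leukocyte-rich libraries were of Akr1c12, Igfbp3, Muc5b (adjusted p = 0.171), Myrf, Igkc, Lamp3, Fasn, Elovl6 and Cyp2f2. With leukocyte genes as a covariate they were of Muc5b (adjusted p = 0.103), Igkc, Tap2, H2-D1, Lamp3, Elovl6 and Cyp2f2, and in a fit of only these groups of Muc5b (adjusted p = 0.073), Hnf4a and Ahsg. The calls lost were 9, 5, 6, 1, 7, 5, 5 and 6 without non-metastatic primary tumours 1, 2, 3, 4, 5, 6, 8 and 10.

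Metastatic and non-metastatic primary tumours were compared to ask whether a primary tumour that has spread differs from one that has not. With limma 0 genes passed the threshold, 2406 had an unadjusted p under 0.05, and the smallest adjusted p was 0.191. Several gene groups passed as sets by camera at the preset correlation, but none of those named for this comparison passed with an estimated correlation. Proliferation genes were higher, 0 of 25 over all genes but 14 adjusted over the list alone (median 0.789, camera adjusted p = 1.52e-12, but adjusted p = 0.371 with an estimated correlation). The mitotic genes Bub1 and Ccnb2 were at 1.08 and 1.27 and Mki67 at 0.98. Hypoxia and glycolysis genes were higher, 0 of 20 and 10 adjusted over the list alone (median 0.579, camera adjusted p = 2.94e-07, but adjusted p = 0.329 with an estimated correlation). Matrix remodelling genes moved likewise, 0 of 22 and 8 adjusted over the list alone (median 0.9, camera adjusted p = 1.31e-06, but adjusted p = 0.329 with an estimated correlation). The glycolytic genes Pgk1 and Ldha were at 1.19 and 0.60, and the protease inhibitor and receptor genes Timp1, Serpine1 and Plaur at 2.37, 1.75 and 1.14. Mesenchymal genes were higher, 0 of 14 and 2 adjusted over the list alone (median 0.855, camera adjusted p = 0.000317, but adjusted p = 0.594 with an estimated correlation). Fn1 was at 1.60. Fibroblast and vessel muscle genes were higher with them, 0 of 14 and 1 adjusted over the list alone (median 0.434, camera adjusted p = 0.0231, but adjusted p = 0.716 with an estimated correlation and 0.0746 among genes with a mean of 5 TPM or more).

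Alveolar type 2 genes were lower as a set, with 0 of 20 members past either adjustment (median -1.06, camera adjusted p = 8.76e-10, but adjusted p = 0.329 with an estimated correlation). Lipid synthesis genes moved likewise, 0 of 18 and 6 adjusted over the list alone (median -0.297, camera adjusted p = 2.94e-07, but adjusted p = 0.129 with an estimated correlation). Fasn was at -0.71 and Elovl1 at -0.82. Hmga2 was at 69.6 ± 61.4 TPM in metastatic and 18.2 ± 14 TPM in non-metastatic primary tumours (SD, n = 9 and 10; log2 fold change 1.79, SE 0.52, adjusted p = 0.204). The intermediate filament gene Vim, which marks mesenchymal cells (ENSMUSG00000026728, chromosome 2, 13573927 to 13582826), was at 538 ± 638 and 98 ± 136 TPM (2.32, adjusted p = 0.227). Runx2 (1.25, adjusted p = 0.23), Nkx2-1 (-1.04, adjusted p = 0.516), Sftpc (-1.77, adjusted p = 0.35) and the epithelial cadherin gene Cdh1 (-0.11, adjusted p = 0.954) did not pass either. The count stayed 0 under every other scaling, filter, covariate and weighting tried, with the mouse as a block and without both nearly identical libraries. Without metastatic primary tumour 3 it was 32, 26 higher and 6 lower, and Pgk1 (1.37, adjusted p = 0.0275) and Timp1 (2.67, adjusted p = 0.0404) then passed.

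**Figure D2:**
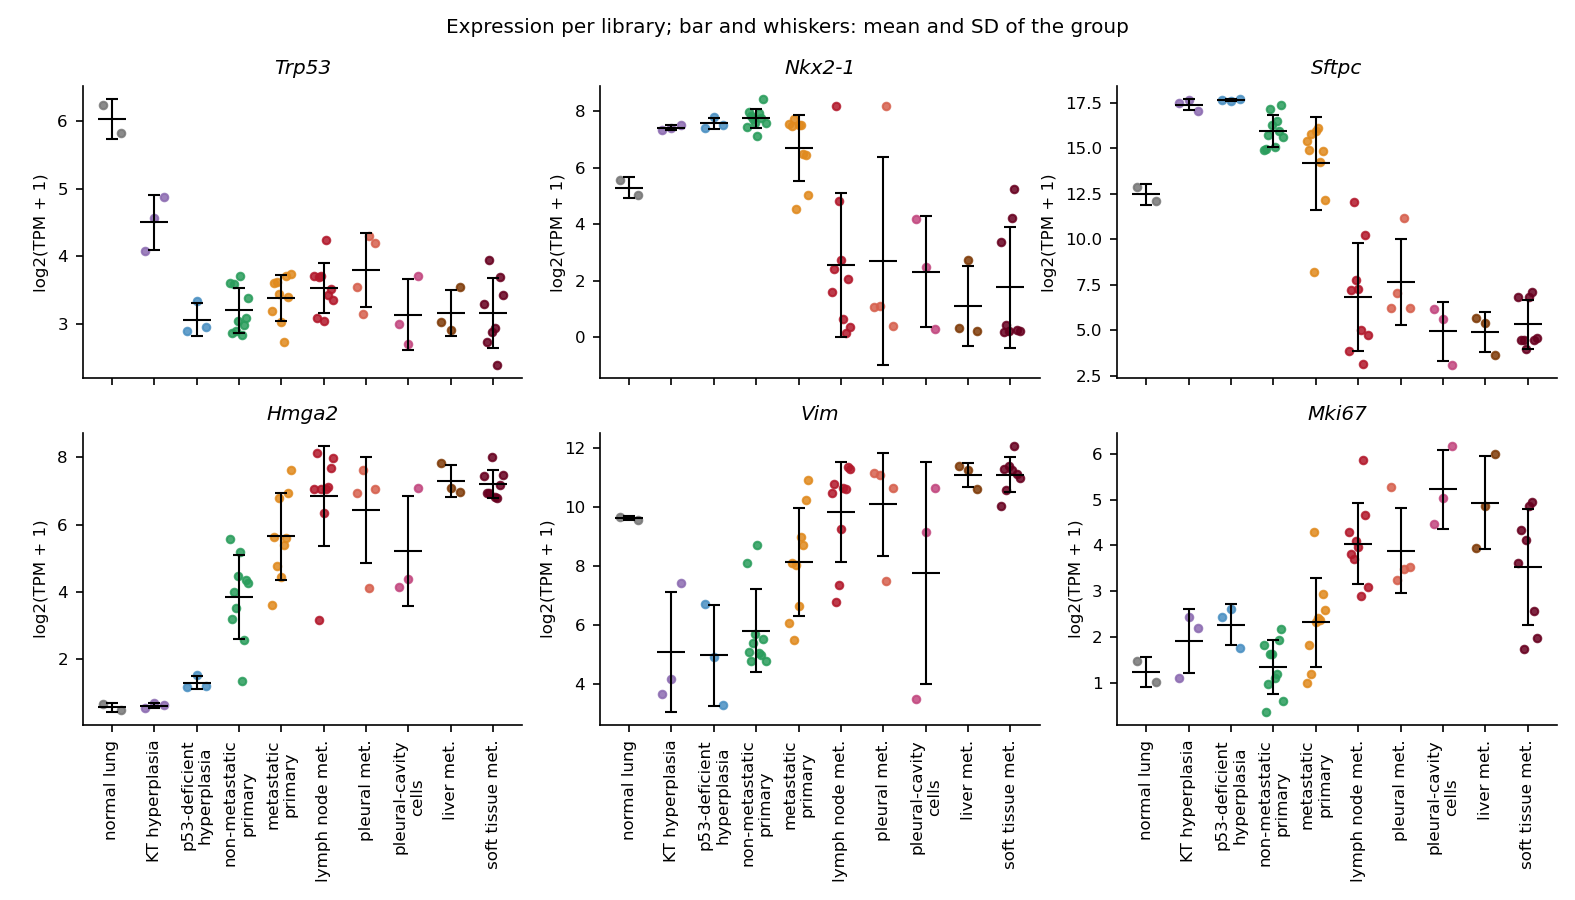
log2(TPM + 1) of Trp53, Nkx2-1, Sftpc, Hmga2, Vim and Mki67 in each library (points) along the groups, with the mean and SD of each group (bar and whiskers). Nkx2-1 lay at 139 to 342 TPM in non-metastatic primary tumours and at 0.116 to 293 TPM in metastases.

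Metastases differed from non-metastatic primary tumours in 10121 genes, 4862 higher and 5259 lower. The alveolar program fell. Nkx2-1, the homeobox gene that maintains lung epithelial identity (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908), was at 29.1 ± 83.2 TPM in metastases and 219 ± 54.5 TPM in the tumours (SD, n = 12 mice and 10 tumours; log2 fold change -5.60, SE 0.62, adjusted p = 7.54e-09). Lymph node and pleural metastasis 3, of mouse CC0349, kept Nkx2-1 at 291 and 293 TPM, while their Sftpc was at 4187 and 2335 TPM, against 53930 and 56260 TPM in the non-metastatic and metastatic primary tumours of that mouse. Without the metastases of CC0349 the Nkx2-1 mean was 5.19 ± 7.93 TPM (n = 11) and the log2 fold change -6.15. Foxa2, a lung endoderm factor, fell by 2.32. All 20 alveolar type 2 genes fell by both adjustments (median -6.32, camera adjusted p = 3.81e-17, but adjusted p = 0.319 with an estimated correlation), Sftpc from 75480 ± 48510 to 362 ± 922 TPM, or to 97.9 ± 137 TPM without the metastases of CC0349. The surfactant protein genes Sftpc, Sftpa1, Sftpb and Sftpd had log2 fold changes of -9.89, -9.58, -8.83 and -7.10, the phosphate transporter gene Slc34a2 of -8.38, Napsa of -7.64 and the chemokine gene Cxcl15 of -7.44. Of 17 alveolar type 1 genes 13 fell and 1 rose by both adjustments (median -1.77, camera adjusted p = 3.35e-05, but adjusted p = 0.319 with an estimated correlation). Ager was at -7.31 and Hopx at -5.37. Of 15 airway genes 8 fell and 0 rose by both adjustments, Scgb1a1 by 5.37 (median -2.4, camera adjusted p = 0.00234, but adjusted p = 0.394 with an estimated correlation).

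In their place rose genes of mesenchymal cells and of cell division. Of 14 mesenchymal genes 12 rose and 0 fell, and 13 adjusted over the list alone (median 1.96, camera adjusted p = 0.000173, but adjusted p = 0.418 with an estimated correlation), among them Vim (4.29, from 98 ± 136 to 1737 ± 1015 TPM), S100a4 (3.98), fibronectin Fn1 (2.62) and Prrx1 (2.03). Of 21 epithelial junction and keratin genes 14 fell and 0 rose, and 15 adjusted over the list alone (median -1.71, camera adjusted p = 0.00109, but adjusted p = 0.633 with an estimated correlation). The epithelial regulators Grhl2 and Esrp1 were at -3.16 and -3.13 and Cdh1 at -1.26. All 25 proliferation genes rose by both adjustments (median 2.26, camera adjusted p = 1.06e-16, but adjusted p = 0.319 with an estimated correlation). Mki67 was at 2.78, Cdk1 at 2.92, Bub1 at 2.68 and Ccnb2 at 3.09. Matrix remodelling genes rose in 15 of 22 and fell in 2, by both adjustments (median 1.44, camera adjusted p = 0.00191, but adjusted p = 0.418 with an estimated correlation). Loxl2 was at 3.01, Mmp14 at 1.68 and Timp1 at 4.13. Of 20 hypoxia and glycolysis genes 12 rose and 2 fell by both adjustments (median 0.757, camera adjusted p = 0.00722, but adjusted p = 0.614 with an estimated correlation and 0.0598 among genes with a mean of 5 TPM or more). Pgk1 was at 2.21 and Ldha at 1.17.

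Antigen display and lipid genes changed as well. All 9 MHC class II genes fell by both adjustments (median -4.22, camera adjusted p = 2e-08, but adjusted p = 0.319 with an estimated correlation). The invariant chain gene Cd74 was at -6.60 and H2-Eb1 at -5.63. Among MHC class I genes 9 of 12 fell by both adjustments (median -1.36, camera adjusted p = 4.92e-05, but adjusted p = 0.394 with an estimated correlation). Psmb9 was at -3.42 and Tap1 at -2.39. Of 19 cholesterol synthesis genes 16 rose and 0 fell, and 17 adjusted over the list alone (median 0.869, camera adjusted p = 2.47e-06, but adjusted p = 0.396 with an estimated correlation). Sqle and Cyp51 were both at 1.71. Of 18 lipid synthesis genes 11 fell and 2 rose, and 13 and 2 adjusted over the list alone (median -0.865, camera adjusted p = 0.000637, but adjusted p = 0.319 with an estimated correlation). Scd1 was at -3.62 and Fasn at -1.54. Of 16 immediate early genes 11 fell and 2 rose by both adjustments, Fos by 1.75 and Jun by 1.62 (median -1.14, camera adjusted p = 0.0312, but adjusted p = 0.657 with an estimated correlation and 0.0818 without the metastases of mouse CC0349). Of 14 fibroblast and vessel muscle genes 7 rose by both adjustments, Col3a1 by 2.98 and Col5a1 by 3.14 (median 0.929, camera adjusted p = 0.014, but adjusted p = 0.633 with an estimated correlation and 0.0631 among genes with a mean of 5 TPM or more). In contrast 8 of 13 endothelial genes fell by both adjustments, Esam by 3.02 (median -0.514, camera adjusted p = 0.00467, but adjusted p = 0.614 with an estimated correlation).

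Hmga2 rose by 2.89, from 18.2 ± 14 to 141 ± 72.9 TPM, Runx2 by 2.45 and the surface protein gene Cd109 by 1.64. The other large rises were in Inhba, an activin subunit (4.63), the annexin gene Anxa8 (4.60), Dynap (4.43), the galectin gene Lgals1 (4.25) and the actin-bundling gene Fscn1 (4.10). The kinase gene Jak1 rose by 0.76 and Cdkn2a by 0.95, while Cdkn1a (-1.49), Gata6 (-1.24) and Kras (-0.68) were lower and Trp53 did not pass (0.12, adjusted p = 0.533). Myc rose by 0.63 (adjusted p = 0.0285), but that call was lost without non-metastatic primary tumour 7 or 9, without the metastases of mouse CC0302 or CC0543, after quantile normalization, in a fit of only these groups (adjusted p = 0.0662) and with genes detected as a covariate. Of the 55 named genes past the threshold Cdh1 was also lost with that covariate. The count was 6451 among genes with a mean of 5 TPM or more, and with genes detected as a covariate 4484 were higher and 2735 lower.

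Metastases also differed from metastatic primary tumours, with 6315 genes past the threshold, 2322 higher and 3993 lower, and most groups moved as above. Of 20 alveolar type 2 genes 19 fell by both adjustments (median -5.18, camera adjusted p = 2.37e-21, but adjusted p = 0.145 with an estimated correlation). Sftpc, Sftpa1, Sftpb, Slc34a2 and Cxcl15 were at -8.12, -7.90, -7.76, -7.17 and -6.37. Of 17 alveolar type 1 genes 12 fell by both adjustments, Ager by 6.16 (median -1.56, camera adjusted p = 1.87e-06, but adjusted p = 0.25 with an estimated correlation). All 25 proliferation genes rose by both adjustments (median 1.52, camera adjusted p = 2.94e-18, but adjusted p = 0.25 with an estimated correlation). The cyclin genes Ccna2 and Ccnb1 were at 2.08 and 2.05, Cdk1 at 1.87, Mki67 at 1.80 and Foxm1 at 1.48. Of 9 MHC class II genes 8 fell by both adjustments, Cd74 by 5.52 and H2-Aa by 5.43 (median -3.28, camera adjusted p = 1.29e-09, but adjusted p = 0.237 with an estimated correlation). Of 21 epithelial genes 16 fell by both adjustments (median -1.86, camera adjusted p = 1.74e-05, but adjusted p = 0.599 with an estimated correlation). Grhl2 was at -2.70, Cldn3 at -3.32 and Cdh1 at -1.16. Of 14 mesenchymal genes 4 rose, and 7 adjusted over the list alone (median 1.02, camera adjusted p = 0.000864, but adjusted p = 0.567 with an estimated correlation). S100a4 was at 2.44, Zeb1 at 1.21 and Prrx1 at 0.99. Fibroblast and vessel muscle genes were higher with them, 3 of 14 by both adjustments (median 0.495, camera adjusted p = 0.0298, but adjusted p = 0.64 with an estimated correlation, 0.0878 among genes with a mean of 5 TPM or more and 0.0825 without the metastases of mouse CC0349), and did not pass under either other scaling.

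Of 19 cholesterol synthesis genes 13 rose by both adjustments, Sqle by 0.90 (median 0.597, camera adjusted p = 1.87e-06, but adjusted p = 0.444 with an estimated correlation). Of 16 immediate early genes 12 fell, and 13 adjusted over the list alone (median -1.29, camera adjusted p = 9.57e-05, but adjusted p = 0.533 with an estimated correlation). Fos was at -1.75 and Jun at -1.65. Nkx2-1 fell by 4.56 (SE 0.64, adjusted p = 3.17e-06), Foxa2 by 1.73, Cdkn1a by 1.72 and Gata6 by 0.84. Vim rose by 1.97 (SE 0.73, adjusted p = 0.0354), Dpysl3, of the cytoskeleton, by 2.10, Fscn1 by 2.07 and Runx2 by 1.21. Hmga2 (1.10, adjusted p = 0.0825) and Cd109 (1.04, adjusted p = 0.055) did not pass. Both passed without the metastases of mouse CC0349 (1.38, adjusted p = 0.0147, and 1.18, adjusted p = 0.0239), and Cd109 also under both other scalings. The higher and lower counts were 3140 and 3633 after median-of-ratios scaling, 3333 and 2688 after quantile normalization, and 807 and 608 with genes detected as a covariate, and 4142 genes passed among those with a mean of 5 TPM or more. With the mouse as a block the calls of Cdh1 (-0.91, adjusted p = 0.0888) and Prrx1 (0.91, adjusted p = 0.0748) were lost. Of the 30 named genes past the threshold 25 stayed past it with any 1 sample left out, the others being Vim, Runx2, Cdh1, Gata6 and Prrx1. Of these 3, 4, 4, 4, 1 and 2 were lost without metastatic primary tumours 1, 2, 3, 5, 6 and 7. They were 4, 3, 3, 1, 2, 3, 2 and 4 without the metastases of mice CC0133, CC0302, CC0543, CC0545, CC0560, CC0772, CC0802 and CC1032. With genes detected as a covariate 12 of the 30 calls were lost. In a fit of only these groups 7 were lost, those of S100a4 (adjusted p = 0.0515), Vim (adjusted p = 0.0648), Runx2, Cdh1, Gata6, Zeb1 and Prrx1.

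**Figure D3:**
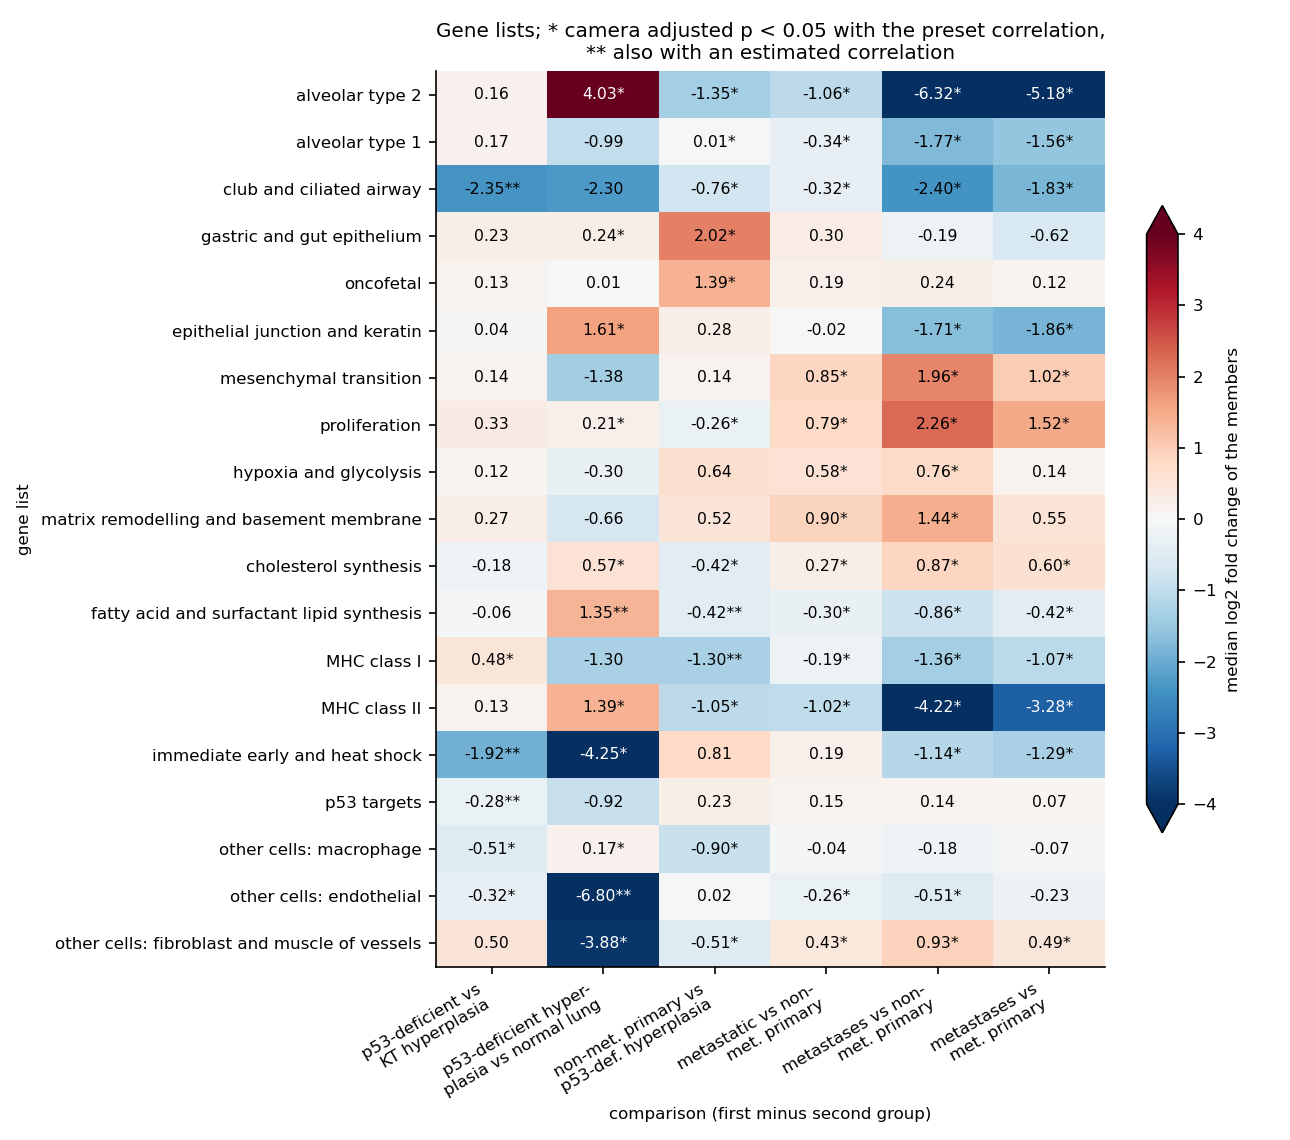
Median log2 fold change of the members of 19 gene lists (lines) in the 6 stage comparisons (columns), with asterisks for camera adjusted p under 0.05. The alveolar type 2 list goes from 4.03 in p53-deficient hyperplasia against normal lung to -6.32 in metastases against non-metastatic primary tumours.

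The changes in metastatic primary tumours and in metastases, both against non-metastatic primary tumours, were alike across the 18342 genes. The log2 fold changes correlated at r = 0.841, against a mean of 0.51 and a highest value of 0.534 in 100 simulations of unchanged groups with shared controls, and 81.4% of genes had the same sign, against 67% simulated. The covariance was 0.263, against 0.029 simulated, a difference of 0.234. With the controls split into separate sets for each comparison the median r was 0.73 (0.646 to 0.793) and the median covariance 0.249. Genes are not independent replicates, and many metastases come from the same mice as the metastatic primary tumours. The simulations drew every sample independently, so they leave out the likeness that shared mice give. Splitting the controls does not remove it either.

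**Figure D4:**
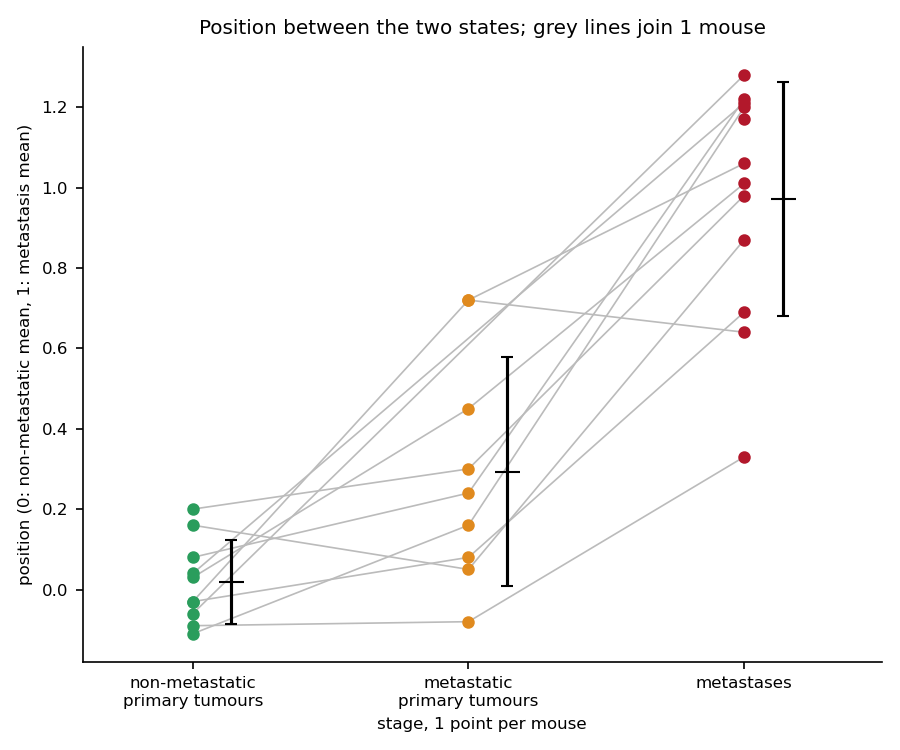
Position of each mouse's samples on the line from the mean of non-metastatic primary tumours (0) to the mean of metastases (1), computed with the own mouse left out of both means, with mean and SD beside each group and grey lines joining samples of 1 mouse. Metastatic primary tumours spread from -0.08 to 0.72 and non-metastatic ones from -0.11 to 0.2.

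Placed on the line from non-metastatic primary tumours (0) to metastases (1), metastatic primary tumours had a mean position of 0.29 ± 0.29 and non-metastatic ones of 0.02 ± 0.1 (SD, n = 9 and 10), a difference of 0.27 (exact permutation test, two-sided, p = 0.00748). That test does not use the pairing. Within the 8 mice with both kinds of tumour the mean difference was 0.21 (exact sign flips, two-sided, p = 0.0234), and within the 6 left without CC0299 and CC0302 it was 0.26 (exact p = 0.0312, the smallest that 6 mice can give). Of the 9 metastatic primary tumours 5 lay above every non-metastatic one. Normal lung 1 and 2 lay at 0.35 and 0.36 on the same line, so a middle position does not by itself show a move toward metastases. Metastases resembled the primary tumour of their own mouse. Deviations from the group means correlated at a mean r of 0.409 between metastases and the metastatic primary tumour of the same mouse and -0.047 with those of other mice. The difference was 0.456 (exact permutation of the mouse codes, two-sided, p = 2.76e-06, the smallest that 9 mice can give), and 7 of 9 were closest to their own. Given a positive r within mice, centring on group means alone makes the value for other mice slightly negative, so that value adds little. For the metastatic and non-metastatic primary tumours of 8 mice the difference was 0.237 (0.208 and -0.029, exact permutation p = 0.012), and 3 of 8 were closest to their own. Over the 2000 most variable genes it was 0.227 (exact permutation p = 0.0639), and without mice CC0299 and CC0302, which hold the nearly identical libraries, 0.325 (exact permutation p = 0.00278).

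Sites of metastasis were compared to ask how the place of growth affects cancer cells. Pleural and lymph node metastases differed in 1 gene. Aspn, which encodes the matrix protein asporin and was named after its values were seen (ENSMUSG00000021388, chromosome 13, 49544443 to 49567565), was at 3.35 ± 0.744 TPM in pleural and 0.633 ± 0.353 TPM in lymph node metastases (SD, n = 4 and 9; log2 fold change 1.43, SE 0.21, adjusted p = 0.0138). Fibroblast and vessel muscle genes were higher as a set, 0 of 14 over all genes and 7 adjusted over the list alone (median 1.18, camera adjusted p = 1.86e-19, and adjusted p = 0.0424 with an estimated correlation). Lum was at 1.74 and Tagln at 1.27. Endothelial and mesothelium genes were higher with them, 0 of 13 and 0 of 9 past either adjustment (medians 0.249 and 0.108, camera adjusted p = 4.09e-06 and 0.0285, but adjusted p = 0.274 for both with an estimated correlation). Mesothelium genes did not pass with the mouse as a block (median 0.0951, camera adjusted p = 0.0754) or with leukocyte genes as a covariate (camera adjusted p = 0.0547). Immediate early genes were lower as a set, 0 of 16 past either adjustment (median -0.769, camera adjusted p = 1.75e-10, but adjusted p = 0.229 with an estimated correlation), and Nkx2-1 did not pass (0.14, adjusted p = 1). Hypoxia and glycolysis genes did not pass as a set without the mouse in the fit (median -0.134, camera adjusted p = 0.679) but did with the mouse as a block (median -0.51, camera adjusted p = 4.66e-15, at the preset correlation alone). Their list mean was lower in the pleural metastasis of each of the 4 pairs (6.07 against 6.82, 6.80 against 7.41, 6.12 against 6.80 and 6.39 against 6.67). In all, 289 genes had an unadjusted p under 0.05. The count was 0 with the mouse as a block (Aspn 1.46, adjusted p = 0.296), with a pseudocount of 0.1, among genes with a mean of 5 TPM or more, in a fit of only these groups, and without pleural metastasis 3 (Aspn adjusted p = 0.184) or 4 (adjusted p = 0.143). It was 6 with the mouse as a random effect, and 3 and 2 without pleural metastases 1 and 2.

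Tumour cells from the pleural cavity held less RNA of stromal genes than lymph node metastases. Of 14 fibroblast and vessel muscle genes 3 fell, and 10 adjusted over the list alone (median -1.76, camera adjusted p = 4.82e-15, but adjusted p = 0.0696 with an estimated correlation). The collagen genes Col3a1, Col1a1 and Col1a2 had log2 fold changes of -4.72, -4.39 and -4.39, Col3a1 going from 120 ± 81.8 to 6.76 ± 10.6 TPM (SD, n = 9 and 3). Postn did not pass (-3.44, adjusted p = 0.0704). Matrix remodelling genes were lower as a set, 0 of 22 and 5 adjusted over the list alone, with Mmp2 at -3.18 and Tnc at -3.58 (median -1.06, camera adjusted p = 2.07e-05, but adjusted p = 0.0696 with an estimated correlation). Mesenchymal genes moved likewise, 1 of 14 and 5 adjusted over the list alone (median -1.4, camera adjusted p = 2.07e-05, but adjusted p = 0.424 with an estimated correlation). Fn1 fell by 3.44 and Vim did not pass (-2.08, adjusted p = 0.523). Egr2, a growth-induced transcription factor gene, fell by 5.07 (SE 0.55, adjusted p = 7.43e-05). Serpinf1 was at -5.10 and the immunoglobulin gene Igkc, which is uncertain, at -6.78. Sprr1a, of squamous cell envelopes, was at 4110 ± 3512 against 282 ± 170 TPM (3.83), and Lcmt2 (2.05), Ppp1r15b (1.06) and Lrrfip2 (1.06) rose.

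In all, 21 genes passed, 5 higher and 16 lower. With the mouse as a block the count was 175, 87 higher and 88 lower, so the leaning to lower genes was not kept, and Serpinf1 (adjusted p = 0.0785), Lrrfip2 (adjusted p = 0.065) and Fn1 (adjusted p = 0.0599) did not pass. It was 430 with the mouse as a random effect (222 higher, 208 lower), 92 with a pseudocount of 0.1, 132 with array weights, 6 with genes detected as a covariate, and 1 in a fit of only these groups. It was 2 without pleural-cavity sample 1 or 2, 528 without pleural-cavity sample 3 (300 higher, 228 lower), and 59, 32, 13 and 13 without lymph node metastases 4, 5, 6 and 9. Of the 11 named genes past the threshold Egr2 alone stayed past it with any 1 library left out. Without pleural-cavity sample 1 or 2 the calls lost were 10, and they were 3, 3, 2, 3, 2 and 3 without lymph node metastases 1, 2, 3, 6, 8 and 9. In a fit of only these groups 10 were lost and with genes detected as a covariate 7.

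Soft tissue and lymph node metastases differed in 2 genes, with 470 at an unadjusted p under 0.05. The immunoglobulin light chain gene Igkc, a product of B cells, was at 4.83 ± 10.9 TPM in soft tissue and 651 ± 1330 TPM in lymph node metastases (SD, n = 6 and 9; log2 fold change -6.76, SE 0.97, adjusted p = 0.00838), and Aspn was higher by 1.10 (adjusted p = 0.0461). Of 7 B cell genes 0 passed over all genes and 2 fell adjusted over the list alone (median -0.714, camera adjusted p = 7.1e-06, but adjusted p = 0.789 with an estimated correlation). Ighm was at -2.53 and Jchain at -1.50. Lymph node metastasis 8 stood apart in these genes. Without it the list median was -0.437 and Igkc in lymph node metastases was at 212 ± 182 TPM (n = 8). Nkx2-1 did not pass (-1.03, adjusted p = 1). With the mouse as a block 0 genes passed (Igkc -7.24, adjusted p = 0.0641; Aspn 1.18, adjusted p = 0.0903), as with genes detected as a covariate, and 5 passed with the mouse as a random effect. Proliferation genes did not pass as a set without the mouse in the fit (median -0.249, camera adjusted p = 0.181) but were lower with the mouse as a block (median -0.37, camera adjusted p = 0.000302, at the preset correlation alone). The count was 1, Igkc, without lymph node metastasis 1, 3, 4, 5, 6 or 8, soft tissue metastasis 1 or 2 or the soft tissue metastases of mouse CC1032. Aspn lost its call in 11 of the 15 fits with 1 mouse's sample left out (highest adjusted p = 0.249), among them those without lymph node metastasis 2 and without the soft tissue metastases of mouse CC0802, where the count stayed 2. The count was also 1 without a filter, among genes with a mean of 5 TPM or more, in a fit of only these groups and with leukocyte genes as a covariate.

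Liver and soft tissue metastases differed in 0 genes with limma, and 1339 had an unadjusted p under 0.05. Proliferation genes were higher in liver metastases as a set, 0 of 25 past either adjustment (median 1.43, camera adjusted p = 1.51e-12, but adjusted p = 0.429 with an estimated correlation), with Plk1, Aurka and Mki67 at 1.87, 1.79 and 1.43 (adjusted p = 0.674 for each). These sites share 1 mouse, CC0543, where the list mean was 5.23 in the liver and 4.90 in soft tissue, so site and mouse can hardly be told apart. Fibroblast and vessel muscle genes were lower, 0 of 14 and 4 adjusted over the list alone (median -1.04, camera adjusted p = 3.26e-09, but adjusted p = 0.303 with an estimated correlation). Postn was at 1.37 ± 0.381 against 57 ± 61.1 TPM (SD, n = 3 and 6; -4.01, adjusted p = 0.174) and Col1a1 at -2.84 (adjusted p = 0.631). Hepatocyte genes were higher, 0 of 14 and 5 adjusted over the list alone (median 0.552, camera adjusted p = 7.09e-05, but adjusted p = 0.303 with an estimated correlation and 0.483 among genes with a mean of 5 TPM or more). Albumin Alb was at 9.12 ± 8.41 against 2.30 ± 4.84 TPM, Fgg at 0.89, and Apoc3 at 1.71 ± 2.08 TPM and listed at 0 in soft tissue metastases. Alb was at 3.48, 18.8 and 5.10 TPM in liver metastases 1, 2 and 3 and at 12.15 TPM in soft tissue metastasis 3, the highest of that site. It was at 2.55 to 127.4 TPM in non-metastatic and 0 to 139.7 TPM in metastatic primary lung tumours, so its RNA is not particular to the liver. The count was 9 without a filter, 3 with every library as its own sample, 8 with the mouse as a random effect and 4 with array weights. It was 3, 3, 2, 5 and 1 without liver metastases 1, 2 and 3 and soft tissue metastases 2 and 4.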

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

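The tests of the nearly identical libraries, of airway genes in KT hyperplasia, of 1 library counted in both groups and of positions within mice were chosen only after the result was seen, while the splits of the samples, the power of the fit and the spread of positions over all mice were planned. The test by relatedness to mouse CC0299 was changed once after its first result, by leaving the nearly identical libraries out of the group means, with the same verdict, and so was the test of RNA composition, from a p-value to a list median.

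Of 180 sets of replicate values 17 held 1 library far from the others, against 9 that chance alone gives at about 1 in 20. Pleural metastasis 3 had 15300 genes at 1 TPM or more (nearest 13700) and an alveolar type 1 list mean of 4.15 (nearest 2.25, log2 as for all list means here), and soft tissue metastasis 3 had 7.8% of TPM in mitochondrial genes (nearest 5.52). Lowest of their groups were epithelial genes in metastatic primary tumour 9 (4.86, nearest 5.93), MHC class II genes in metastatic primary tumour 4 (1.81, nearest 4.31), p53 targets in non-metastatic primary tumour 9 (3.19, nearest 3.57), cholesterol genes in lymph node metastasis 9 (4.08, nearest 4.66), mitochondrially encoded genes in lymph node metastasis 7 (10.4, nearest 11.5) and immediate early genes in pleural metastasis 4 (4.9, nearest 5.23). Lymph node metastasis 8 was highest in leukocyte (3.38, nearest 1.74), T cell (1.86, nearest 1.11) and B cell genes (2.62, nearest 1.15), and lymph node metastasis 3 in endothelial genes (1.12, nearest 0.781). Non-metastatic primary tumour 9 was highest in leukocyte (2.22, nearest 1.7), macrophage (2.91, nearest 1.86) and neutrophil genes (1.5, nearest 0.852), and metastatic primary tumour 4 in neutrophil genes (1.94, nearest 0.962).

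The libraries labelled non-metastatic primary tumour 1 and metastatic primary tumour 2 matched far beyond any other pair. Of 1875 low genes 99.8% lay within 10% of each other, against 29.5% in the next pair, which is consistent with 1 library under both labels. Separate but alike tumours can be excluded as the cause, since the SD of the log2 ratio, 0.0145, is far below 0.301 for tumours of 1 mouse. That the values belong to mouse CC0299 can be excluded too: autosomal deviations correlated better with mouse CC0302 by 0.24, Xist was at 0.277 TPM against 525 to 874 in the other CC0299 libraries, and Eif2s3y at 36.2 TPM against 0. Why the values occur under both labels was not tested.

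For the count of 0 genes between metastatic and non-metastatic primary tumours, 95% of simulated 4-fold changes were recovered. The simulation used a spread pooled over all groups and the same change in every metastatic primary tumour. It therefore speaks against too few samples only for large changes that all these tumours share. For uneven changes it cannot decide, and Vim and Timp1 differed by more than 4-fold without passing. The library present in both groups is not the sole cause, since the count stayed 0 without it. Its part is not settled, since the smallest adjusted p of limma then went from 0.191 to 0.0821. Uneven positions of metastatic primary tumours stay open. Their distance from the median was 0.22 on average against 0.083 (exact permutation, two-sided, p = 0.0251), but that test takes tumours of 1 mouse as unrelated, and within the 8 mice with both kinds the distance differed by 0.1 (exact sign flips, two-sided, p = 0.195).

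For the fall of airway genes between KT and p53-deficient hyperplasia, unsorted lung cells in the KT samples can be excluded as the whole cause, since endothelial genes lay a median of -5.94 from the airway genes relative to normal lung. A shift of RNA composition, which moves all genes of a library alike, can be excluded as the whole cause, since the airway list median was -2.49 after median-of-ratios scaling against -2.35 before, while the median of all genes was 0.0236 against 0.0449. Airway cells in the KT samples stay open, although per the labels Tomato-positive cancer cells were purified, a sort that should remove airway cells without the reporter. That 86.7% of the 15 airway genes were 2-fold or more higher there restates the pattern and cannot tell such cells from airway gene expression in the lesion cells. The p53 genotype as a cause was not tested.

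Samples were regrouped while keeping as many pairs of 1 mouse apart as in the real grouping. For non-metastatic primary tumours against p53-deficient hyperplasia, 1 of 100 splits, the real one, reached 2070 genes (highest other 92). For metastases against non-metastatic primary tumours 1 of 100 reached 10121 (highest other 4755), and against metastatic primary tumours 1 of 100 reached 6315 (highest other 3281). For soft tissue against lymph node metastases 1 of 100 reached 2 (highest other 0). In each the real grouping gave more genes than any other split tried, a share of 1 in 100. That concerns the count and not the single genes called. The soft tissue count is moreover 0 with the mouse as a block (Igkc adjusted p = 0.0641, Aspn adjusted p = 0.0903). Splits were too few for a share under 0.05 in p53-deficient against KT hyperplasia (1 of 10 reached 249, highest other 222), pleural against lymph node metastases (2 of 16 reached 1, highest other 1) and pleural-cavity cells against lymph node metastases (1 of 8 reached 21, highest other 0). Where the real count was 0, all 100 splits of the kinds of primary tumour (highest 2) and all 42 of liver and soft tissue metastases (highest 1) reached it, as any split must.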

How the results depend on the processing

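The fits without the nearly identical libraries, without leukocyte-rich libraries and without mouse CC0349, CC0302 or CC0299 were tests chosen after seeing the data, and all others were planned. Of 6544 repeats of named genes 6045 gave the same call, 39 a stronger one, 460 a weaker one and 0 turned, and of 4352 repeats of gene lists 3931 were the same, 120 stronger, 289 weaker and 12 turned. A change of sign counted as turned only if either fit passed the threshold. Genes named by size had been chosen for keeping their sign with any sample left out, and many repeats are such fits. The 0 was thus partly fixed in advance. The cause of the changed calls was not tested.

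Genes past the threshold, by setting, were as follows where the count moved more than 1.5 times. For p53-deficient against KT hyperplasia (249) the pseudocount gave 160, a mean of 5 TPM 9, only these groups 3, array weights 548 and leaving out leukocyte-rich libraries 148. Against normal lung (8370) a mean of 5 TPM gave 4662 and genes detected 3742. For non-metastatic primary tumours against p53-deficient hyperplasia (2070) a mean of 5 TPM gave 1378, median-of-ratios 856, quantile 822, array weights 7917, the leukocyte covariate 1145, genes detected 295, leaving out the nearly identical libraries 1324 and leukocyte-rich ones 288. For metastases a mean of 5 TPM gave 6451 against non-metastatic (10121) and 4142 against metastatic primary tumours (6315), the latter 1415 with genes detected. For pleural against lymph node metastases (1) the pseudocount, a mean of 5 TPM, only these groups and the block gave 0 and the random effect 6. For pleural-cavity cells (21) the pseudocount gave 92, only these groups 1, the random effect 430, the block 175, array weights 132 and genes detected 6. For soft tissue against lymph node metastases (2) no filter, a mean of 5 TPM, only these groups, the leukocyte covariate and leaving out lymph node metastasis 8 gave 1, the random effect 5, and the block and genes detected 0. For liver against soft tissue metastases (0) no filter gave 9, every library as its own sample 3, the random effect 8 and array weights 4. The random effect had a correlation of 0.36 in stages and 0.7 in sites.

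Leaving out 1 sample gave 156 to 331 genes for p53-deficient against KT hyperplasia, 6063 to 8019 against normal lung, 308 to 3200 for non-metastatic primary tumours against hyperplasia, 0 to 32 between kinds of primary tumour, 9652 to 10565 and 4918 to 7271 for metastases against non-metastatic and metastatic primary tumours, 0 to 3 for pleural, 2 to 528 for pleural-cavity and 1 to 2 for soft tissue against lymph node samples, and 0 to 5 for liver against soft tissue.

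With an estimated correlation 132 of 140 list calls were lost. Of the same 140 the pseudocount lost 9, no filter 8, median-of-ratios 13, quantile 19, only the groups compared 7, array weights 14 and genes detected 16. Fewer list calls could be repeated in other settings. Of these a mean of 5 TPM lost 25 of 127, the leukocyte covariate 13 of 138 and the block 10 of 82. Lists that turned are given by their median. In p53-deficient against KT hyperplasia these were macrophage genes with array weights (0.369) and neutrophil genes without leukocyte-rich libraries (-0.12), against normal lung mitochondrially encoded genes after quantile normalization (-0.182), and in non-metastatic primary tumours T cell genes without leukocyte-rich libraries (0.246). For pleural metastases epithelial genes turned with the block (-0.47) and for pleural-cavity cells proliferation genes with genes detected (0.149). For soft tissue against lymph node metastases they were alveolar type 2 (0.1) and airway genes (0.08) with genes detected, and airway (-0.194), mesenchymal (-0.212), epithelial (0.322) and matrix genes (-0.268) with the block.

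Splitting the controls took the correlation of metastatic primary tumours and metastases from 0.841 to 0.73. The likeness of primary tumours of 1 mouse was 0.227 over 2000 genes against 0.237. Lists in fits other than the main ones were judged at the preset correlation alone. With the mouse as a block some lists gained such a call, given by their median. In metastatic against non-metastatic primary tumours these were epithelial (-0.326) and immediate early genes (0.342), and in metastases against metastatic primary tumours matrix (0.652) and endothelial genes (-0.281). Against lymph node metastases they were hypoxia (-0.51) and ribosomal genes (-0.146) for pleural metastases, and alveolar type 2 (-0.499), oncofetal (-0.443), neuroendocrine (-0.554) and immediate early genes (-0.458) for pleural-cavity cells. For soft tissue they were oncofetal (-0.384), proliferation (-0.37), neuroendocrine (-0.552), immediate early (0.194) and endothelial genes (0.101). Of the 10 lists that lost a call, that of mesothelium genes in pleural metastases is given with the results and the others are not. Beyond these values and those with the results, the block changed no other call given in the results.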

Other observations

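Single mice departed from their group in the alveolar regulator Nkx2-1. Lymph node metastasis 3 and pleural metastasis 3, both of mouse CC0349, held 291 and 293 TPM of Nkx2-1, where the next highest metastasis, soft tissue metastasis 6, held 37.1 TPM. Among metastatic primary tumours, 4 and 9 (mice CC0355 and CC1032) held 22.5 and 31.6 TPM and all others at least 86.5 TPM. On the line from non-metastatic primary tumours to metastases, those tumours were both at 0.72 and the metastases of CC0349 at 0.33.

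Sex-linked genes also varied within mice. In CC0374 the X-inactivation gene Xist was at 526 and 516 TPM in the primary tumours, 66.2 TPM in lymph node metastasis 5 and 3.06 TPM in pleural-cavity sample 2. In CC0349 the Y-linked gene Kdm5d was at 12 TPM in non-metastatic primary tumour 3 and at 2.38 to 2.84 TPM in the other samples.

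The tests of this part were all chosen only after the result was seen, except for the spread of positions over all mice, which was planned. If a primary tumour's position reflects how far the cells that spread had moved, tumours with higher positions may have metastases with higher positions. Over 9 mice r was 0.28 (exact permutation, two-sided, p = 0.459) and rho 0.27 (exact p = 0.493), and r was 0.69 without the 2 farthest mice (exact p = 0.0845), so no relation was shown. The spread of positions that this rests on differed between the kinds of primary tumour with mice taken as unrelated (exact permutation, two-sided, p = 0.0251), and within mice no such difference was shown (exact sign flips, two-sided, p = 0.195). Dissection of separate regions of metastatic primary tumours, with Nkx2-1 and Vim measured in each, could tell whether the spread lies between tumours or within them.

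If KT hyperplasia contains airway cells because lesions of those mice grow around bronchioles, Scgb1a1 and Foxj1 would be found in lesions that touch an airway and be absent from others of either genotype. Staining of hyperplasia of both genotypes for the Scgb1a1 product would test it.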
